A study of Mus musculus with 11 samples.

How the data were processed

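Hepatic gene expression was measured on 11 Illumina BeadChip arrays in 4 groups: lean FXR-WT (2 arrays), lean FXR-K217Q (3), obese FXR-WT (3) and obese FXR-K217R (3). Every array has its group, construct and replicate number from the labels, and 0 columns of the tables were left unmatched. The labels do not say whether replicates are separate animals, so the p-values measure only the spread between these samples. They give 8 weeks as the age on every array. Probes had a mean of 41.9 to 44.0 beads per array, and 18263 to 19500 probes were detected on each. The number of arrays, rather than of beads, limits the precision of each value.

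The deposited table of non-normalized values gives, per the file headers, a mean bead intensity for each probe and array, with the number of beads and the standard error over beads. Per the file headers, it also gives a detection p-value for each probe and array. Per the labels, biotin-labelled cRNA was made with the Illumina TotalPrep kit, and the software that summarised the beads is not given in the sources used here. The authors also gave normalized values on a log2 scale, whose columns have nearly the same quartiles, and per the submitters' processing notes limma 3.12.3 was used, without the function or its settings. Both deposited copies of the normalized log2 values are identical (largest difference 0). They differ from the values computed here by 0.0271 at most.

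The intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with the detection p-values in place of control probes and an offset of 16. Of 45281 probes, 21485 had a detection p-value under 0.05 on at least 2 arrays and were kept. For each gene symbol the probe with the highest mean over all arrays was kept, which left 15469 genes, 4774 of them with clone or locus symbols only. Of these genes, 4256 had several probes past the filter. Symbols are those of the deposited table. They were matched to the gene table of assembly GRCm38.p6 for names and synonyms only, where 9785 of the tested symbols are current. Current symbols are given beside older ones. A spreadsheet had turned the symbols of 40 probes into dates, and these were not renamed. No coordinates are printed, and the genome build behind the probes is not given in the sources used here.

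One linear model per gene was fitted with limma (lmFit and eBayes) to all 11 arrays with a mean for each group, so that the 4 groups share 1 estimate of the spread. The contrasts were lean FXR-K217Q minus lean FXR-WT, obese FXR-K217R minus obese FXR-WT, obese FXR-WT minus lean FXR-WT, and the FXR-K217R change minus the FXR-K217Q change. Tests are two-sided, and Benjamini-Hochberg adjustment at 5% FDR was made within each contrast over all genes. A change is a difference of mean log2 values. Where no array of a group detected a gene, the fold is a lower bound: the other group's mean was set against the dimmest detected value on those arrays, and it is written as at least that many fold.

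A set of 36 gene lists (784 members, of which 668 were tested) covers metabolism, bile acids, inflammation, stress, cell types, clock and sex-biased genes. Each was tested with limma's camera at a preset correlation of 0.01 between genes, and beside it with an estimated correlation and with fry, adjusted over the 36 lists. Fry asks whether a list moves on balance one way, and in its mixed form in either direction, without comparing the list with other genes. The count of members past 5% was also taken adjusted over the list alone.

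Genes were named by a rule. It takes, of the genes past 5% FDR whose groups do not overlap, the 10 largest rises and the 10 largest falls, without clone or locus symbols, or, if none pass, the 5 rises and 5 falls with the smallest unadjusted p. It always takes Nr1h4, Nr0b2, Abcb11, Cyp7a1, Cyp8b1, Tnf, Il1b, Ccl2, Saa1 and Lcn2. Of each list described it takes up to 4 members past 5% FDR with the largest change or, if none pass, up to 2 with the smallest unadjusted p. Genes named as the calls of an alternative setting, Dbp and the members of the clock index fall outside it and were chosen after their values were seen. The design, the lists, this rule and all alternatives but 2 were fixed before the data were examined. Of the genes this rule takes, 2 are not reported here. For 72 pairs of a named gene and a comparison another probe of the gene was tested. In 5 of these pairs a probe had the opposite sign, 1 of them for a called gene (Acot2).

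The correlations of changes across genes were set against 1000 simulations of groups without differences, with the same sharing of arrays. The procedure was tested on simulated data of 15469 genes, 200 of them changed. At a change of 1 on the log2 scale it recovered 70% of changed genes for lean FXR-K217Q, 77% for obese FXR-K217R and 76% for obesity, and at a change of 2 it recovered 98%, 99% and 97%. False calls numbered 5, 6 and 4. Noise was drawn independently for each gene and array, without arrays that stand apart, and 200 true changes ease the adjustment. The shares therefore do not tell how many changes were missed in a comparison with few or no calls.

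The alternatives were quantile normalization without background correction, the authors' normalized values, median scaling, no filter, detection on every array, every probe tested, eBayes with trend and robust options, array weights, the replicate number as a block, only the groups compared in the fit, leaving out each array in turn, and for lists the estimated correlation and fry. After seeing the data 2 were added: the clock index as a covariate, and leaving out both lean FXR-K217Q replicate 3 and obese FXR-WT replicate 1, the arrays least like their own groups. A block for the slide was not run, since the slide of each array is not given in the sources used here.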

Results

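Liver RNA of male C57BL/6J mice was measured on 11 Illumina BeadChip arrays. The mice carried adenovirus for FXR (Nr1h4), the nuclear receptor that bile acids activate, and had all received GW4064, a synthetic FXR agonist, at 30 mg/kg. Lean mice expressed FXR-WT (2 arrays) or FXR-K217Q (3 arrays), in which glutamine takes the place of a lysine and resembles acetylated lysine. Obese mice expressed FXR-WT (3 arrays) or FXR-K217R (3 arrays), in which arginine takes its place and cannot be acetylated. Between 18263 and 19500 of the 45281 probes were detected per array, and 15469 genes were tested. Values are normalized log2 intensities, and a change is a difference of group means on the log2 scale.

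Nr1h4 itself averaged 12.30 ± 0.10 (SD, n = 2) in lean FXR-WT, 12.20 ± 0.19 (SD, n = 3) in lean FXR-K217Q, 12.12 ± 0.16 (SD, n = 3) in obese FXR-WT and 12.42 ± 0.09 (SD, n = 3) in obese FXR-K217R livers, and no comparison passed for it. Whether its probe reads the delivered transcript, the mouse's own or both is not given in the sources used here. The transcript of Nr0b2, the corepressor SHP that FXR induces, was detected on 0 of the 11 arrays, so it was not tested.

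The first principal component held 34.6% of the variance and the second 15.7%. Lean FXR-K217Q replicate 3 had the lowest mean correlation with the arrays of its own group (0.981) and correlated best with lean FXR-WT replicate 2 (r = 0.988 across genes), while lean FXR-K217Q replicates 1 and 2 correlated best with each other (r = 0.992). All 3 obese FXR-K217R arrays also correlated best with an array of another group, obese FXR-WT. Clock transcripts differed within groups: Dbp, a clock-driven transcription factor, was 10.45 on lean FXR-K217Q replicate 3 against 12.87 and 12.85 on replicates 1 and 2, and 10.74 on obese FXR-WT replicate 1 against 12.67 and 12.88 on replicates 2 and 3. Arntl, the clock activator BMAL1, lay the other way, at 8.09 and 7.49 on those arrays. A clock index (mean of Dbp, Per3, Nr1d1 and Nr1d2 minus mean of Arntl and Clock) averaged -0.38 ± 0.16 (SD, n = 2) in lean FXR-WT, 0.48 ± 1.21 (SD, n = 3) in lean FXR-K217Q, 0.67 ± 1.32 (SD, n = 3) in obese FXR-WT and 1.78 ± 0.26 (SD, n = 3) in obese FXR-K217R livers. Both lean FXR-WT arrays (-0.49 and -0.27) lay nearer to lean FXR-K217Q replicate 3 (-0.92) than to its replicates 1 and 2 (1.07 and 1.29). The index was 0.86 (SE 0.88) higher in lean FXR-K217Q and 1.05 (SE 0.88) higher in obese FXR-WT than in lean FXR-WT livers. Both comparisons with lean FXR-WT may thus also hold a difference of clock state. These clock genes were chosen after their values were seen.

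**Figure D1:**
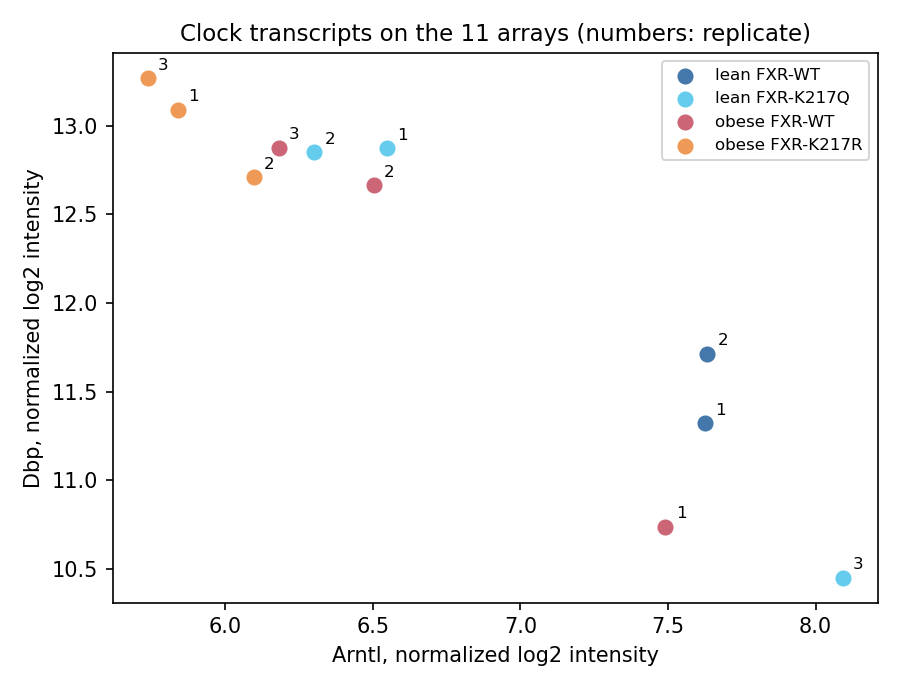
Normalized log2 intensity of Dbp (vertical axis) against Arntl (horizontal axis), with 1 point per array, coloured by group and numbered by replicate. Lean FXR-K217Q replicate 3 (Dbp 10.45) and obese FXR-WT replicate 1 (Dbp 10.74) lie apart from the other arrays of their groups. Both lean FXR-WT arrays (Dbp 11.32 and 11.71) lie between them and the remaining arrays in Dbp.

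FXR-K217Q was compared with FXR-WT in lean mice to ask what the acetylation mimic does to liver transcripts where there is no obesity. Lipid droplet and PPAR-gamma genes were higher with FXR-K217Q: the 16 measured members had a median change of 0.46, and 13 were positive. Cidec, a lipid droplet protein that favours fat storage, averaged 9.03 ± 0.27 (SD, n = 3) against 7.42 ± 0.46 (SD, n = 2), a change of 1.60, and Adfp (now Plin2), which coats lipid droplets, changed by 0.97. Cholesterol biosynthesis genes lay lower: all 22 measured members were negative, with a median of -0.72, and Acat2, which makes acetoacetyl-CoA, averaged 10.63 ± 0.03 (SD, n = 3) against 11.44 ± 0.06 (SD, n = 2). Ltf, the neutrophil granule protein lactoferrin, had the smallest unadjusted p of all genes (1.01e-05), at 5.22 ± 0.18 (SD, n = 3) against 7.48 ± 0.20 (SD, n = 2).

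No single gene passed 5% FDR in limma (0 of 15469 genes, smallest adjusted p = 0.149), while 1113 had an unadjusted p under 0.05 against 773 expected from chance, and 0 of the 21485 probes passed when tested singly. Of the lipid droplet genes 0 passed over all genes and 5 rose adjusted over the list alone (camera adjusted p = 4.8e-06, adjusted p = 0.0344 with an estimated correlation), and this list passed in all 25 alternative settings with medians of 0.26 to 0.49. Settings that leave out an obese array or change only the test keep the same lean changes, so they add no separate support. Of the cholesterol genes 0 passed over all genes and 13 fell adjusted over the list alone. Their camera adjusted p was 4.54e-19, with adjusted p = 0.12 with an estimated correlation and 0.0419 in fry. With both arrays that stand apart left out, a choice made after seeing the data, 2 genes passed, Krt23 and LOC211591, both higher. Single arrays of the obese groups also changed the count: without obese FXR-K217R replicate 3 Cd99l2 passed as higher, and without obese FXR-WT replicate 3 Ltf passed as lower.

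Neutrophil markers split in lean FXR-K217Q livers. Ltf changed by -2.26 and Mpo, the granule enzyme myeloperoxidase, by -2.38 (not detected on the 3 FXR-K217Q arrays, so at least 3.38-fold lower; its other probes gave -1.94 and -0.12), both with adjusted p = 0.149. The median of the 11 measured members was only -0.16 and their mean -0.63, with 0 past over all genes and 5 lower adjusted over the list alone. The list passed in camera (adjusted p = 0.00622) but not otherwise (adjusted p = 0.438 with an estimated correlation), and fry's test for changes in either direction gave 2.71e-07. The median turned positive and the camera call was lost without lean FXR-K217Q replicate 2 (0.07) and on probes detected on every array (0.19). That filter drops Camp, Ltf, Mpo and Ngp, whose means lay lower with FXR-K217Q. The median was -0.24 and -0.44 without FXR-K217Q replicates 1 and 3, and -0.06 and -0.26 without lean FXR-WT replicates 1 and 2. Erythroid markers had a median of -0.09 and a mean of -0.24 (SE 0.23), with 6 of 8 members negative. As a list they gave no call beside the neutrophil markers (camera adjusted p = 0.375), with 0 past over all genes and 1 lower adjusted over the list alone.

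Several stress and metabolic groups lay higher with FXR-K217Q, with 0 members past over all genes in each and no call left under an estimated correlation. Fatty acid oxidation and PPAR-alpha targets had a median of 0.24, with 24 of 27 members positive and 0 past adjusted over the list alone (camera adjusted p = 3.23e-05, adjusted p = 0.438 with an estimated correlation). In that group Fgf21, a fasting hormone made by the liver, changed by 1.85 and its regulator Ppara by 0.68. NRF2 and glutathione genes, which answer oxidative stress, had a median of 0.50 (Osgin1 1.04, Srxn1 1.04, 0 past adjusted over the list alone, camera adjusted p = 0.000131, adjusted p = 0.693 with an estimated correlation). Immediate early genes had a median of 0.42, with Egr1, a rapidly induced transcription factor, at 1.52 and Junb at 0.87. Of these, 2 of 13 rose adjusted over the list alone (camera adjusted p = 0.000662, adjusted p = 0.29 with an estimated correlation). Single arrays moved these medians: NRF2 genes to 0.29 without FXR-K217Q replicate 1 and 0.83 without replicate 3, and immediate early genes to 0.25 without FXR-K217Q replicate 1, 0.62 without lean FXR-WT replicate 1 and 0.24 without lean FXR-WT replicate 2, where the call was lost.

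Inflammatory, cell type and lipogenesis groups passed with the preset correlation and not with an estimated one. NF-kB inflammatory genes had a median of 0.24, with 23 of 30 positive and 0 past over all genes or adjusted over the list alone (camera adjusted p = 0.000662, adjusted p = 0.693 with an estimated correlation). In that group the monocyte chemokine Ccl2 changed by 1.38 (SE 0.39) and Irf1 by 0.51 (SE 0.16). The cytokines Tnf and Il1b gave 0.54 (SE 0.28) and 0.60 (SE 0.43), and the acute phase genes Saa1 and Lcn2 gave -0.07 (SE 0.18, with -1.46 on the other Saa1 probe) and -0.55 (SE 0.35). Stellate cell and matrix genes had a median of 0.33 (Col1a1 1.04, Timp1 0.96, camera adjusted p = 0.0101, adjusted p = 0.799 with an estimated correlation) and endothelial markers -0.23 (Oit3 -0.50, Gpr182 -0.37, camera adjusted p = 0.0101, adjusted p = 0.693 with an estimated correlation). De novo lipogenesis had a median of -0.33, with Acacb at -0.42 and Pklr at 0.78 (camera adjusted p = 0.0101, adjusted p = 0.693 with an estimated correlation). In these 3 groups 0 members passed over all genes or adjusted over the list alone. All 4 calls hung on single arrays. Without FXR-K217Q replicate 1 or lean FXR-WT replicate 2 those of NF-kB genes (medians 0.12 and 0.13) and stellate cell genes (0.09 and 0.01) were lost, and without lean FXR-WT replicate 1 these medians were 0.41 and 0.57. The endothelial call was lost without FXR-K217Q replicate 3 (-0.14) or lean FXR-WT replicate 1 (-0.24), and that of lipogenesis without FXR-K217Q replicate 3 (-0.19) or lean FXR-WT replicate 2 (-0.23).

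Genes of bile acid metabolism, the best known field of FXR action, gave no call in lean mice. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, changed by -0.44 (SE 0.89), Cyp8b1, which makes cholic acid, by 0.57 (SE 1.24) and Abcb11, the bile salt export pump, by -0.02 (SE 0.26). Without FXR-K217Q replicate 3 the signs of Cyp7a1 (0.11) and Abcb11 (0.10) turned. FXR-induced targets had a median of 0.06 (camera adjusted p = 0.275), with Sdc1 at -0.65 and Sqstm1 at 0.42, and bile acid synthesis genes -0.01 (camera adjusted p = 0.861). The other genes with the smallest unadjusted p were the retinol dehydrogenase Rdh11 (-0.84), the T cell receptor segment Tcrb-V8.3 (-1.76), the kinase subunit Camk2b (1.52) and Serpina12 (1.15), all with adjusted p = 0.149. Of the 36 lists, 10 passed with the preset correlation, 1 with an estimated correlation and 2 in fry. Fry's test for changes in either direction also passed for fatty acid oxidation (0.00328), immediate early genes (0.00933), de novo lipogenesis (0.0423) and glucose metabolism (0.0423).

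**Figure D2:**
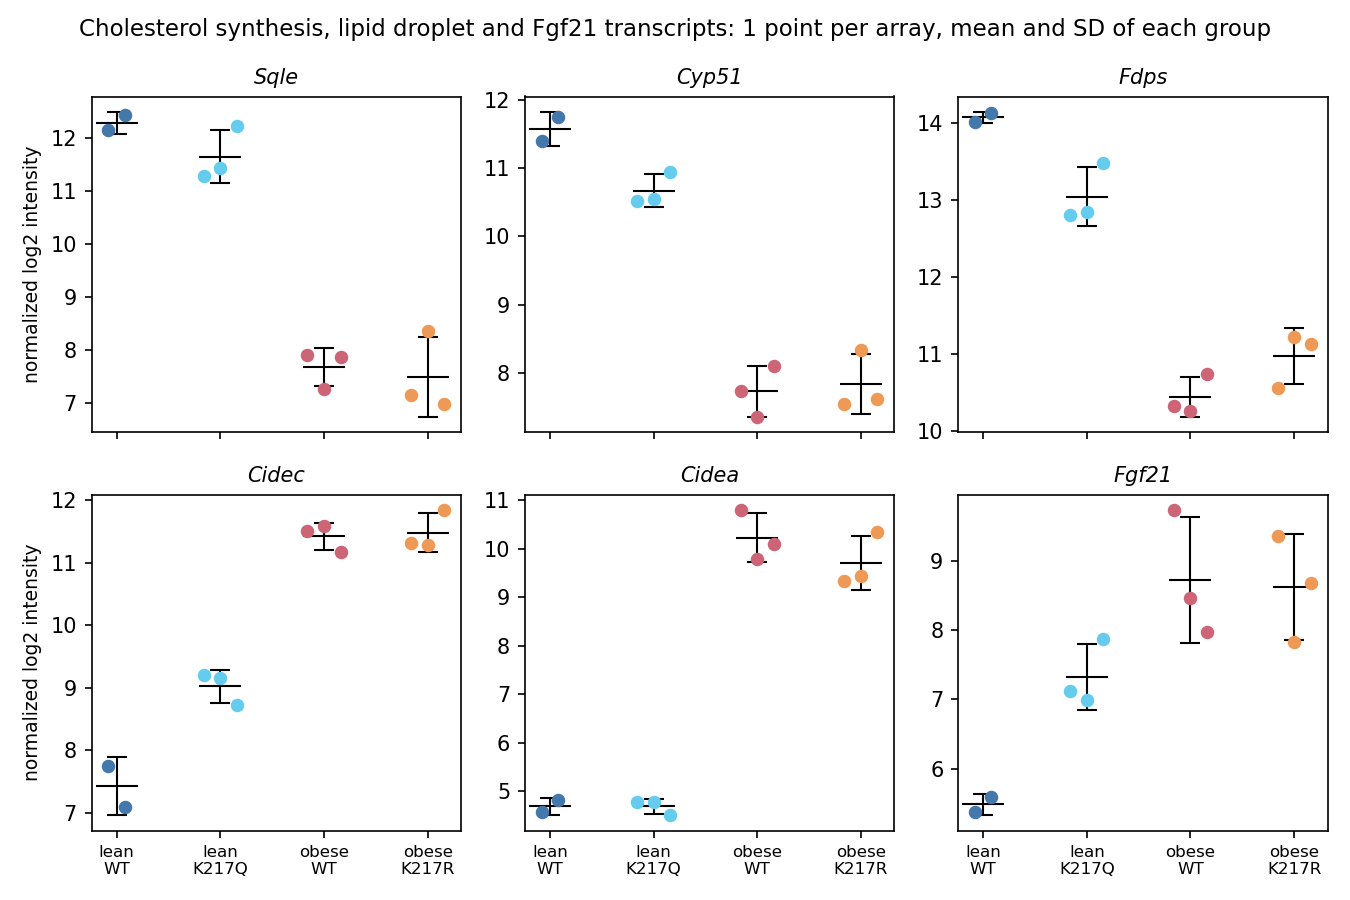
Normalized log2 intensity (vertical axes, 1 scale per gene) of 3 cholesterol synthesis genes, 2 lipid droplet genes and Fgf21 in the 4 groups, with 1 point per array and bars for the group mean and SD. Cidec averaged 7.42 in lean FXR-WT, 9.03 in lean FXR-K217Q and 11.42 in obese FXR-WT livers, and Sqle averaged 12.28 in lean and 7.68 in obese FXR-WT livers.

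FXR-K217R was compared with FXR-WT in obese mice to ask what an FXR that cannot be acetylated at this site does in obesity. The arrays do not measure the acetylation of FXR. Neutrophil transcripts fell: 6 genes passed, all lower with FXR-K217R and all 6 from the neutrophil list. Ltf averaged 6.22 ± 0.35 (SD, n = 3) against 9.46 ± 0.54 (SD, n = 3), which is 9.51-fold lower (adjusted p = 0.00162), and Mpo averaged 5.32 ± 0.64 (SD, n = 3) against 8.54 ± 0.60 (SD, n = 3), which is 9.32-fold lower (adjusted p = 0.00632; its other probes gave -3.02 and -1.07). Camp, the antimicrobial peptide cathelicidin, changed by -3.02 (adjusted p = 0.00885) and Ngp, a neutrophil granule protein, by -2.87 (adjusted p = 0.00307). The calprotectin subunits S100a9 and S100a8, abundant in neutrophils and monocytes, changed by -2.56 (adjusted p = 0.00253) and -2.29 (adjusted p = 0.0135). Ngp was detected on 1 of the 3 FXR-K217R arrays and Camp and Mpo on 2 of 3, so the size of their falls is measured partly against background.

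Each of the 6 genes was lower on all 3 FXR-K217R arrays than on all 3 FXR-WT arrays, where chance alone separates 3 arrays from 3, in either direction, in 10% of genes. The 6 were picked by their p-values on these same arrays, so their separation adds no support. Of the 11 measured neutrophil markers 6 fell and 5 did not pass over all genes, and 8 fell adjusted over the list alone, with a median of -2.32. The list passed in camera (adjusted p = 9.88e-24, adjusted p = 0.00653 with an estimated correlation) and in fry (0.000261), and in all 25 alternative settings, with medians of -2.52 to -1.37. Settings that leave out a lean array or change only the test keep the same obese changes, so they add no separate support. Erythroid markers had a median of 0.03 and a mean of -0.07 beside this fall (camera direction down, adjusted p = 0.928), and the clock index was 1.11 higher with FXR-K217R (SE 0.79). In limma 682 genes had an unadjusted p under 0.05 against 773 expected from chance, and 7 probes passed when tested singly. The count was 3 without obese FXR-K217R replicate 1 (Ltf, Ngp and S100a9), 10 without lean FXR-K217Q replicate 3 (the 6 with Cd177, Ela2, Mmp9 and Retnlg), 2 with only the obese arrays in the fit (Ltf and S100a9) and 2 on probes detected on every array (S100a8 and S100a9). That last filter removed Camp, Ltf, Mpo and Ngp from the test.

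Markers of T and NK cells, of macrophages and monocytes and of MHC class II presentation lay slightly higher with FXR-K217R, with 0 past over all genes and no call left under an estimated correlation. T and NK cell markers had a median of 0.43, with 17 of 19 positive, and the T cell surface genes Cd6 and Cd2 at 0.75 and 0.68 (camera adjusted p = 1.32e-06, adjusted p = 0.705 with an estimated correlation). MHC class II presentation genes also had a median of 0.43 (H2-DMb2 0.57, H2-DMb1 0.49, camera adjusted p = 0.0013, adjusted p = 0.705 with an estimated correlation). Macrophage and monocyte markers had a median of 0.13, with the integrins Itgb2 at 0.54 and Itgax at 0.70 (camera adjusted p = 0.0013, adjusted p = 0.705 with an estimated correlation). In these 3 lists 0 members passed adjusted over the list alone. Much of this came from obese FXR-WT replicate 1, which stands apart: without it the medians were 0.20 for T and NK cells (adjusted p = 0.0333), 0.04 for MHC class II and 0.05 for macrophages and monocytes, the last 2 without a call. Without obese FXR-WT replicate 3 they were 0.65, 0.66 and 0.22. The macrophage and monocyte median was also 0.21 without obese FXR-WT replicate 2, 0.28 without FXR-K217R replicate 3 and 0.05 without FXR-K217R replicate 2, where the call was lost. Kupffer cell markers, of the resident macrophages, lay the other way without a call, with a mean of -0.35 (SE 0.34) and 7 of 9 members negative (Vsig4 -1.13, Clec4f -0.81, camera adjusted p = 0.208).

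NF-kB inflammatory genes had a median of 0.24 with FXR-K217R, 24 of 30 being positive (camera adjusted p = 0.00592, adjusted p = 0.72 with an estimated correlation), and the call was lost without obese FXR-WT replicate 1 (0.05) or FXR-K217R replicate 2 (0.10). Of the list 0 passed over all genes and 1 fell adjusted over the list alone, Mmp9, a matrix protease that neutrophils store in granules, at -1.28 (adjusted p = 0.0602). Tnf changed by 0.61 (SE 0.25), Ccl2 by 0.48 (SE 0.35), Il1b by -0.15 (SE 0.38), Saa1 by 0.02 (SE 0.16, with -0.72 on its other probe) and Lcn2 by -0.17 (SE 0.31), and none passed. The sign of Il1b turned without FXR-K217R replicate 1 (0.23), and that of Lcn2 without FXR-K217R replicate 3 (0.13). Acute phase proteins had a median of -0.32, with Serpina3n at -0.92 and Itih3 at -0.33 (0 past over all genes or adjusted over the list alone, camera adjusted p = 0.00364, adjusted p = 0.72 with an estimated correlation). Their call was lost without obese FXR-WT replicate 1 (-0.18) or FXR-K217R replicate 1 (-0.19).

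Metabolic groups changed little with FXR-K217R, with 0 members past over all genes or adjusted over the list alone in each. Cholesterol biosynthesis had a median of 0.14 (Dhcr7 0.40, Fdps 0.53, camera adjusted p = 0.0107, adjusted p = 0.72 with an estimated correlation), lipid droplet genes 0.19 (G0s2 0.56, camera adjusted p = 0.037, adjusted p = 0.593 with an estimated correlation) and de novo lipogenesis 0.21 (Pklr 0.53, Fads1 0.26, camera adjusted p = 0.00445, adjusted p = 0.705 with an estimated correlation). Amino acid catabolism had a median of -0.12 (Hal -0.60, Aass -0.58, camera adjusted p = 0.0013, adjusted p = 0.705 with an estimated correlation). Unfolded protein response genes had -0.24 (Chac1 -0.47, Hsp90b1 -0.33, camera adjusted p = 0.0101, adjusted p = 0.72 with an estimated correlation) and cell cycle genes 0.28 (Bub1b 0.64, Kif11 0.62, camera adjusted p = 0.0025, adjusted p = 0.72 with an estimated correlation). With the clock index as a covariate these last medians turned to 0.13 and -0.08. Each of these 6 calls was lost when some single arrays were left out. Without obese FXR-WT replicate 1 the calls of cholesterol (0.11), lipogenesis (0.15), amino acid (-0.11), unfolded protein (-0.08) and cell cycle genes (0.15) were lost. Those of cholesterol (0.15), lipid droplet (0.18) and cell cycle genes (0.16) were lost without obese FXR-WT replicate 2. Without obese FXR-WT replicate 3 the lipid droplet call (0.14) was lost, while cholesterol, unfolded protein and cell cycle genes were at 0.23, -0.40 and 0.46. Without FXR-K217R replicate 1 amino acid (-0.04) and cell cycle genes (0.13) lost their calls and cholesterol genes were at 0.23. Without FXR-K217R replicate 2 cholesterol genes (0.05) did. Without FXR-K217R replicate 3 cholesterol (0.17), lipid droplet (0.21), lipogenesis (0.13) and unfolded protein genes (-0.20) did, and amino acid genes were at -0.26. FXR-induced targets had a median of -0.16 (Sdc1 -0.66, Apoc2 -0.43, camera adjusted p = 0.0753), and Cyp7a1, Cyp8b1 and Abcb11 changed by 0.64 (SE 0.80), 1.24 (SE 1.11) and -0.23 (SE 0.23). Without obese FXR-WT replicate 1 all 3 signs turned (-0.39, -0.38 and 0.07). Of the 36 lists, 12 passed with the preset correlation, 1 with an estimated correlation and 1 in fry.

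**Figure D3:**
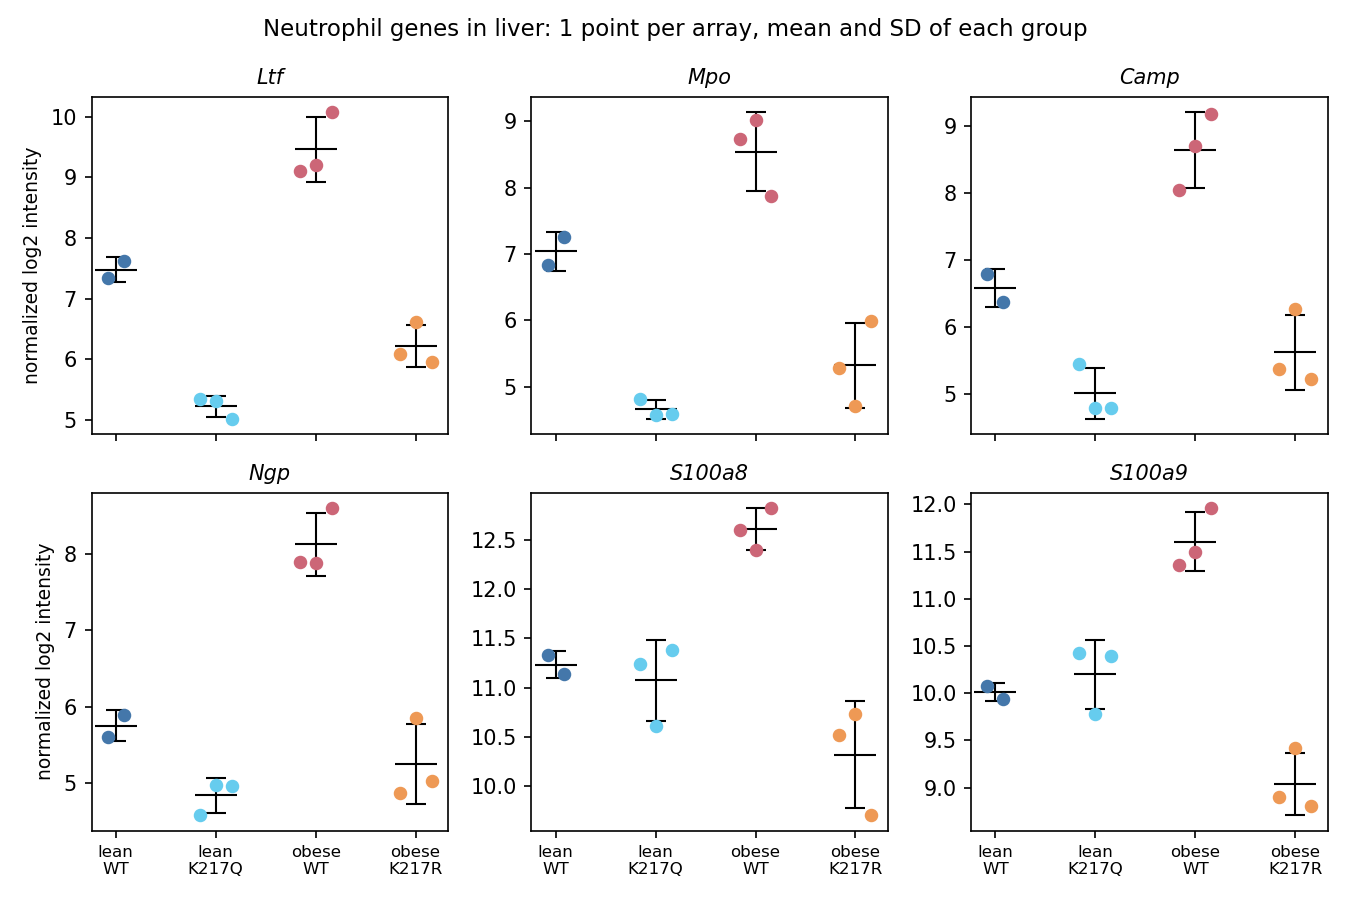
Normalized log2 intensity (vertical axes, 1 scale per gene) of the 6 genes past 5% FDR between obese FXR-K217R and obese FXR-WT livers, in the 4 groups, with 1 point per array and bars for the group mean and SD. All 3 obese FXR-K217R arrays lie below all 3 obese FXR-WT arrays, while lean FXR-K217Q lies below lean FXR-WT for Ltf (5.22 against 7.48) and not for S100a9 (10.20 against 10.01), with no lean gene past 5% FDR.

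Obese FXR-WT livers were compared with lean FXR-WT livers as the background against which both mutants are set. The titles mark obese arrays HFD and lean arrays ND, read here as high-fat and normal diet, so diet and obesity change together and what is called the obesity difference is that of both. Cholesterol synthesis genes fell and lipid droplet genes rose. Sqle, the squalene epoxidase, averaged 7.68 ± 0.36 (SD, n = 3) in obese against 12.28 ± 0.21 (SD, n = 2) in lean livers, which is 24.3-fold lower (adjusted p = 0.000399). Cidea, a lipid droplet protein, averaged 10.23 ± 0.51 (SD, n = 3) in obese livers and was not detected on the 2 lean arrays, so that it was at least 32.8-fold higher (adjusted p = 6.88e-05). Cidec averaged 11.42 ± 0.22 (SD, n = 3) in obese against 7.42 ± 0.46 (SD, n = 2) in lean livers, and Fgf21 was 9.49-fold higher.

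Of 15469 genes 185 passed in limma, 106 higher and 79 lower, 39 of them known only by clone or locus symbols. The largest named falls belong to cholesterol synthesis: Sqle (-4.60), Cyp51 (-3.84), Idi1 (-3.82), Fdps (-3.63), Sc4mol, now Msmo1 (-3.49), Nsdhl (-3.40), Mvd (-3.30) and Lss (-3.28). Of the 22 measured cholesterol biosynthesis genes 17 fell over all genes and 22 adjusted over the list alone, with a median of -2.17 (camera adjusted p = 9.19e-46, adjusted p = 0.0106 with an estimated correlation). Lean FXR-K217Q arrays act on this comparison only through the shared spread, and leaving out a lean FXR-WT array leaves 1 in its group. The count of 185 depended on the arrays and settings used. With the clock index as a covariate, a choice made after seeing the data, the count was 178, with 125 of the 185 kept. It was 36 without lean FXR-WT replicate 2, 60 without lean FXR-WT replicate 1, 52 without obese FXR-WT replicate 2, 62 without obese FXR-WT replicate 3, 283 without lean FXR-K217Q replicate 3, 467 without both arrays that stand apart, 514 with array weights and 110 with only the 2 groups in the fit.

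Genes of fat storage and fat burning rose. Of 16 lipid droplet and PPAR-gamma genes 5 rose over all genes and 10 adjusted over the list alone, with a median of 0.94 (camera adjusted p = 9.32e-13, adjusted p = 0.00334 with an estimated correlation): beside Cidec and Cidea, these include Cfd, the adipocyte protease adipsin (3.54), and S3-12, now Plin4 (1.79). Of 27 fatty acid oxidation and PPAR-alpha targets 7 rose over all genes, and 16 rose and 1 fell adjusted over the list alone, with a median of 0.46 (camera adjusted p = 1.37e-11, adjusted p = 0.0653 with an estimated correlation). Examples are Fgf21 (3.25), the acyl-CoA thioesterase Acot3 (3.19), Pdk4, which spares glucose (2.35), and Acot2 (2.13, detected on 1 of 2 lean arrays, with -0.27 on its other probe), the Acot genes being close paralogs. De novo lipogenesis went both ways: Scd1, which makes monounsaturated fat (1.37), and Elovl5 (0.69) rose and Acss2 (-1.12) fell over all genes, with 3 up and 3 down adjusted over the list alone. Its median was 0.01, its mean -0.02 and its camera direction down (adjusted p = 0.948), and fry's test for changes in either direction gave 1.16e-11.

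Neutrophil markers rose in obese FXR-WT livers: 4 of 11 over all genes and 8 adjusted over the list alone, with a mean change of 1.25 (SE 0.16, camera adjusted p = 7.85e-10, adjusted p = 0.026 with an estimated correlation). The 4 are Ngp (2.37), Camp (2.06), Ltf (1.99) and S100a9 (1.59). Male-biased liver genes fell: 4 of 12 over all genes and 7 adjusted over the list alone, with a median of -0.96 (camera adjusted p = 3.35e-06, adjusted p = 0.0193 with an estimated correlation). The 4 are Susd4 (-1.63), Serpina1e (-1.30) and the complement genes C8b (-1.29) and C6 (-0.72). C8b and C6 are also the 2 of 27 complement and coagulation genes that fell (list median -0.18, 2 lower adjusted over the list alone, camera adjusted p = 0.00611, adjusted p = 0.467 with an estimated correlation). Among 13 immediate early genes Egr1 (1.39) and Fosb (1.13, not detected in lean livers, at least 1.45-fold higher) rose over all genes and 5 adjusted over the list alone, with a median of 0.54 (camera adjusted p = 2.84e-05, adjusted p = 0.0744 with an estimated correlation). Of 27 amino acid catabolism genes 1 fell over all genes, the tyrosine aminotransferase Tat (-1.82, detected on 1 of 3 obese arrays), and 3 adjusted over the list alone, with a median of -0.43 (camera adjusted p = 4.29e-06, adjusted p = 0.467 with an estimated correlation). Tat is also the 1 of 20 hepatocyte markers that fell, a list with a median of -0.04 and a mean of -0.25 (2 lower adjusted over the list alone, camera adjusted p = 0.0472, adjusted p = 0.467 with an estimated correlation). The hepatocyte call, close to the threshold, was lost without any 1 of 7 of the 11 arrays, and the median was -0.10 without obese FXR-WT replicate 1 and -0.02 and -0.09 without lean FXR-WT replicates 1 and 2. Without lean FXR-WT replicate 2 the complement call was lost (-0.07) and amino acid genes were at -0.25, and without lean FXR-WT replicate 1 immediate early genes were at 0.86.

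Other genes of metabolism passed singly. Abcb4, the phospholipid floppase of bile and an FXR target, rose (0.87, adjusted p = 0.0308), as did the cyclin Ccnd1 (1.34), the neurotrophin receptor Ntrk2 (2.40), the serpin Serpina12 (2.27) and the histone gene Hist1h4h (2.30, of a family of near-identical genes). Ppp1r3c, which targets a phosphatase to glycogen (-1.18), and the carboxylesterase Ces6, now Ces2a (-1.10, detected on 1 of 3 obese arrays), fell. Their lists gave no call in camera: FXR-induced targets had a median of 0.09 (1 of 16 rose over all genes, 2 adjusted over the list alone, camera adjusted p = 0.216), bile acid synthesis -0.16 (0 of 16 past over all genes, 2 lower adjusted over the list alone, camera adjusted p = 0.203) and cell cycle genes 0.19 (1 of 30 rose, camera adjusted p = 0.483). Fry's test for changes in either direction passed for FXR-induced targets (0.00108), bile acid and sterol transport (0.0145), glucose metabolism (1.87e-05) and xenobiotic metabolism (0.00438), with members on both sides. Cyp7a1 changed by -1.46 (SE 0.89), Cyp8b1 by -1.73 (SE 1.24) and Abcb11 by -0.20 (SE 0.26), and none passed. The values of Cyp8b1 and Cyp7a1 leaned mainly on obese FXR-WT replicate 1. There Cyp8b1 was 7.71 against 12.39 and 12.75 on replicates 2 and 3, with 12.18 and 13.19 in lean FXR-WT livers. Cyp7a1 was 8.88 against 12.16 and 11.81, with 12.23 and 12.60 in lean FXR-WT livers.

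Inflammatory and stromal groups lay higher in obese livers without a gene past over all genes. Stellate cell and matrix genes had a median of 0.61, with 24 of 25 positive, 4 higher adjusted over the list alone, the collagens Col1a1 at 1.95 and Col4a1 at 0.92 (camera adjusted p = 8.37e-08, adjusted p = 0.472 with an estimated correlation). NF-kB inflammatory genes had a median of 0.21 (Ccl2 1.36, Mmp9 0.85, camera adjusted p = 0.0172, adjusted p = 0.691 with an estimated correlation), with Tnf at -0.06, Il1b at 0.47, Saa1 at -0.22 (-1.64 on its other probe) and Lcn2 at -0.08. Macrophage and monocyte markers had 0.20 (Ly6c1 1.34, Lyz2 0.42, camera adjusted p = 0.0312, adjusted p = 0.684 with an estimated correlation) and interferon response genes 0.27 (Oas3 0.86, Oas2 0.75, camera adjusted p = 0.000909, adjusted p = 0.634 with an estimated correlation). Erythroid markers had -0.41, with the globins Hba-a1 at -0.64 and Hbb-b2 at -0.72 (camera adjusted p = 0.0241, adjusted p = 0.472 with an estimated correlation). Without lean FXR-WT replicate 2 the calls of NF-kB (0.09) and macrophage genes (0.11) were lost. Without lean FXR-WT replicate 1 the erythroid call (-0.35) was lost, and stellate cell and NF-kB genes were at 0.95 and 0.31. Without obese FXR-WT replicate 2 the NF-kB (0.15), macrophage (0.20) and erythroid calls (-0.12) were lost, and without replicate 3 the NF-kB (0.21) and macrophage calls (0.15). Interferon genes were at 0.43 and erythroid markers at -0.70 without obese FXR-WT replicate 1. Of the 36 lists, 16 passed with the preset correlation, 4 with an estimated correlation and 6 in fry.

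**Figure D4:**
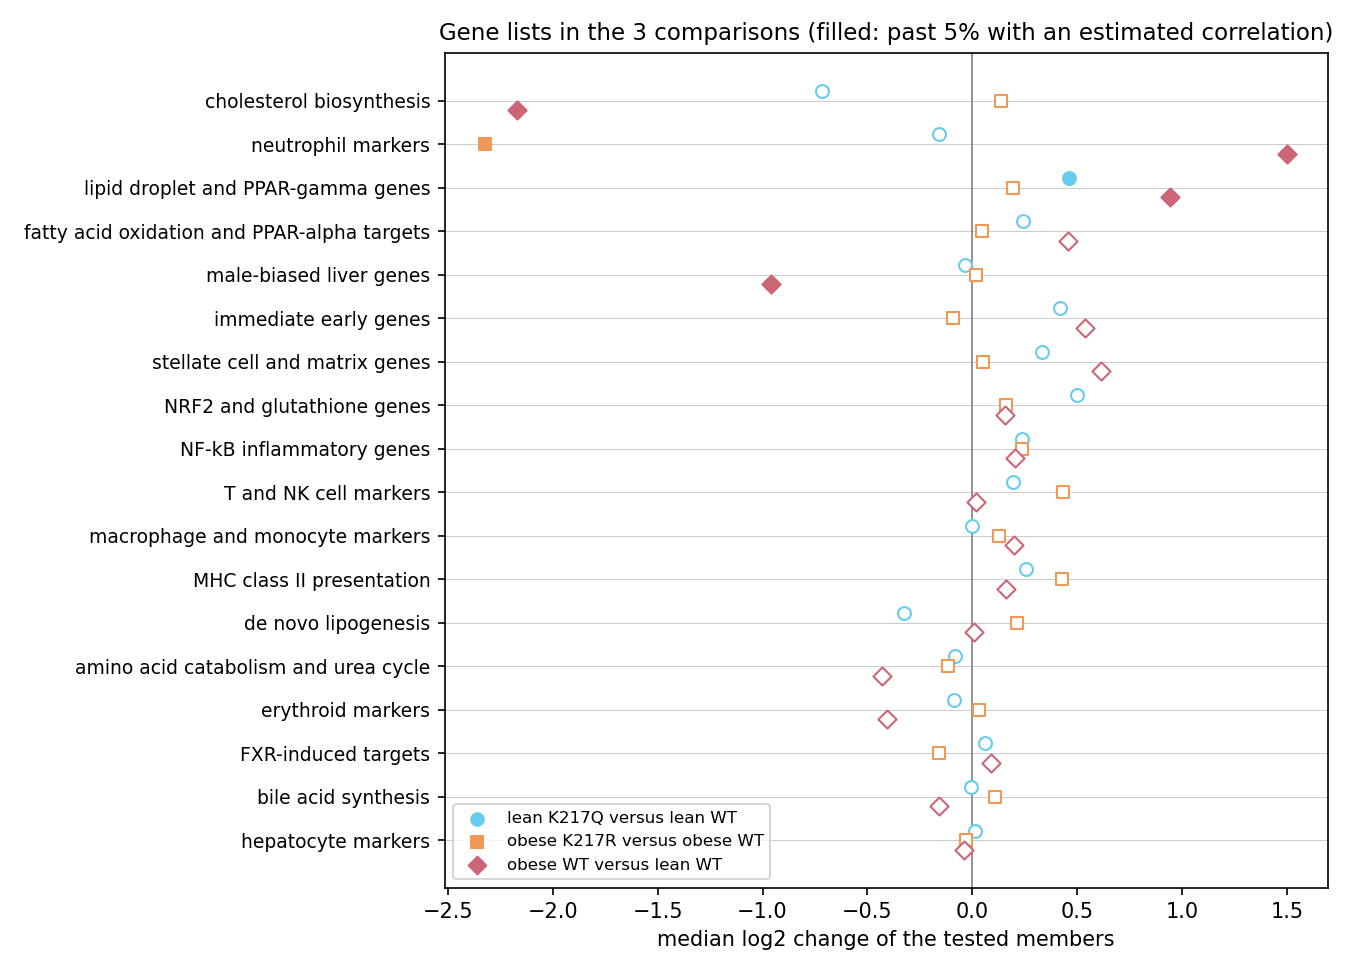
Median log2 change (horizontal axis) of the tested members of 18 gene lists in the 3 comparisons, with 1 symbol per list and comparison, filled where the list passes 5% FDR with an estimated correlation. Neutrophil markers lie at -2.32 in obese FXR-K217R livers and on the positive side in obese FXR-WT livers, and cholesterol biosynthesis at -0.72 in lean FXR-K217Q and -2.17 in obese FXR-WT livers.

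Whether the mutants act along or against the obesity difference was examined gene by gene. Of the 106 genes higher in obese FXR-WT livers 94 had the same sign in lean FXR-K217Q (median 0.41), and of the 79 lower genes 76 did (median -0.54). In obese FXR-K217R 59 of the 106 and 50 of the 79 had the opposite sign (medians -0.05 and 0.07). These counts have no value without an effect beside them: the genes were chosen on a difference that shares the lean FXR-WT arrays with the FXR-K217Q change and the obese FXR-WT arrays with the FXR-K217R change, which by itself favours the same sign in the first and the opposite sign in the second. Across all 15469 genes, which are not independent replicates, the FXR-K217Q change correlated with the obesity difference at r = 0.585 (rho 0.575), where simulated groups without any difference that share the lean FXR-WT arrays gave a mean r of 0.573 (95% range -0.177 to 0.942). The FXR-K217R change correlated with the obesity difference at r = -0.0648 (rho -0.068), and simulated groups that share the obese FXR-WT arrays gave a mean of -0.408 (95% range -0.900 to 0.364), so that the value lies inside that range. The changes of both mutants, which share no array, correlated at r = 0.244 (rho 0.195), inside the simulated 95% range of -0.723 to 0.728. The FXR-K217R relation was near 0 and turned positive with quantile normalization alone (0.0299), on probes detected on every array (0.0118) and without obese FXR-K217R replicate 2 (0.00171).

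Camp, Ltf, Ngp and S100a9 passed both as higher in obese FXR-WT livers and as lower with FXR-K217R. Both comparisons use the 3 obese FXR-WT arrays, which are too few to be divided between them, so a high value on those arrays favours both calls. No value for such an overlap without an effect is given here. The difference between the mutants' changes was itself tested: 0 of 15469 genes passed in limma (smallest adjusted p = 0.122), with 728 at an unadjusted p under 0.05 against 773 expected from chance. Single neutrophil genes passed 5% FDR over all genes with FXR-K217R in obese mice and not with FXR-K217Q in lean mice. In lean mice their list still passed in camera (adjusted p = 0.00622), and mean Mpo, Ltf, Camp and Ngp lay lower with both mutants. For the difference S100a9 alone passed with eBayes trend and robust options, and of the neutrophil list 6 members were lower adjusted over the list alone (fry 0.0301, camera adjusted p = 6.66e-12, adjusted p = 0.0555 with an estimated correlation). In this test mutant and obesity status change together.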

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

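The comparisons of neutrophil genes with red cell and other immune markers, and the use of the clock index as a covariate, were chosen only after the results were seen.

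The change with FXR-K217R in obese mice minus the change with FXR-K217Q in lean mice was tested for each of the 36 lists, and 10 differed in camera with the preset correlation. These were cholesterol biosynthesis (median difference 0.83, adjusted p = 6.6e-21, adjusted p = 0.0949 with an estimated correlation), neutrophil markers (-0.99, adjusted p = 6.66e-12, adjusted p = 0.0555 with an estimated correlation) and de novo lipogenesis (0.59, adjusted p = 4.33e-05, adjusted p = 0.476 with an estimated correlation). Smaller differences were those of endothelial markers (0.29), lipid droplet and PPAR-gamma genes (-0.24), fatty acid oxidation and PPAR-alpha targets (-0.19), immediate early genes (-0.31), B and plasma cell markers (0.46), FXR-induced targets (-0.18) and NRF2 and glutathione genes (-0.33). For the last 7 the preset adjusted p lay between 0.00313 and 0.0301, and with an estimated correlation the adjusted p lay between 0.138 and 0.839. None of the 10 differences held with an estimated correlation, and 0 single genes passed in limma (728 at an unadjusted p under 0.05), with 1, S100a9, under eBayes trend and robust options. In fry neutrophil markers passed (0.0301), and in its test for changes in either direction neutrophil markers (0.00477) and cholesterol genes (0.0144). Adjusted over the list alone, 6 neutrophil and 2 lipid droplet genes were lower and 8 cholesterol genes higher. The mutant and obesity status change together in this contrast, so the design cannot separate them. The groups of 2 or 3 arrays are too small for a test of single arrays that stand far from the others.

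Neutrophil genes fell in obese FXR-K217R livers, with a mean list change of -1.87 (SE 0.14). Less blood in the livers would lower red cell genes too. The erythroid list changed by -0.07 (SE 0.21), which is 1.81 (SE 0.23) above the neutrophil list. A lower share of all immune cells alike would lower other immune markers. Macrophage, monocyte, T and NK cell markers were at 0.31 (SE 0.18), which is 2.18 (SE 0.17) above the neutrophil list. Kupffer cell markers did lie lower at -0.35 (SE 0.34), which is 1.52 (SE 0.32) above it. The neutrophil list was singled out because it fell, so these gaps are no test. What opposes both explanations is only that the erythroid and pooled immune lists did not themselves clearly fall. The pooled value leaned on obese FXR-WT replicate 1. Without that array the macrophage and monocyte median was 0.05 and the T and NK cell median 0.20. With the clock index as a covariate a neutrophil change of -1.83 (SE 0.17) was left. The slope of that covariate rests mainly on lean FXR-K217Q replicate 3 and obese FXR-WT replicate 1, so it cannot decide on time of collection. The 6 arrays make only 10 splits, too few for a share under 0.05: the real split gave 6 genes and 1 of the 10 splits gave as many, the highest other count being 0. Open explanations are fewer neutrophils or neutrophil precursors in these livers, whether from the mutant or from differences between animals or viral doses that the labels do not give, none of which was tested.

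Lean FXR-K217Q arrays moved the way of the obese arrays, with a covariance across genes of 0.0601 between the FXR-K217Q change and the obesity difference. That value lies inside the 95% range of -0.00567 to 0.108 that simulated unchanged groups gave when they shared the lean FXR-WT arrays, so the likeness over all genes may come from those 2 arrays alone. With the clock index as a covariate the cholesterol and lipid droplet lists changed by -0.70 (SE 0.21) and 0.49 (SE 0.10). Without it they changed by -0.75 (SE 0.19) and 0.49 (SE 0.08). Within groups the index varied mainly through lean FXR-K217Q replicate 3 and obese FXR-WT replicate 1, so its slope rests on those arrays. The mean of the cholesterol genes moved opposite ways on them within their groups, so the covariate cannot decide on time of collection. An effect of the mutant on lipid genes stays open and is untested apart from the shared arrays.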

How the results depend on the processing

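The clock index as a covariate and the removal of both arrays that stand apart were chosen after seeing the data, and all other alternatives were planned. Counts below are of genes past 5% FDR.

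The 6 neutrophil genes, all 6 kept, were called with the authors' values, quantile normalization alone, median scaling and no filter. On probes detected on every array 2 were called (S100a8 and S100a9), and with only the obese arrays 2. The former filter drops Camp, Mpo and Ngp, whose tested probes were not detected on every FXR-K217R array, and it also drops Ltf. All 32 calls of named genes that stayed under that filter were kept, so the lower count there comes from the genes removed. Of the 6, 5 were kept with the clock covariate (S100a8 lost), 4 without both arrays that stand apart (Mpo and S100a8 lost), and over single arrays left out 3 to 6, with 3 without obese FXR-K217R replicate 1 and 4 without obese FXR-WT replicate 2. Lean FXR-K217Q gave 1 gene (Ltf) and the difference of changes 1 (S100a9) with eBayes trend and robust options, and lean FXR-K217Q gave 2 without both arrays that stand apart. The obesity count was 514 with array weights (all 185 kept), 467 without both arrays (165 kept) and 110 with only its 2 groups (84 kept). Leaving out 1 array gave 0 to 1 genes in lean FXR-K217Q (1 without obese FXR-K217R replicate 3 or obese FXR-WT replicate 3), 3 to 10 in obese FXR-K217R (3 without its replicate 1, 10 without lean FXR-K217Q replicate 3) and 0 for the difference. For obesity it gave 36 to 283, namely 36 and 60 without lean FXR-WT replicates 2 and 1, 52 and 62 without obese FXR-WT replicates 2 and 3, and 283 without lean FXR-K217Q replicate 3. A lone lean FXR-WT array is then assumed to vary like the other groups. The correlation across genes of FXR-K217R with obesity turned to 0.0299 with quantile normalization alone and 0.0118 on probes detected on every array, was -0.197 without both arrays, and ranged from -0.197 to 0.00171 over single arrays left out. That of FXR-K217Q with FXR-K217R ranged from 0.144 to 0.336, and that of FXR-K217Q with obesity from 0.484 to 0.713. The cause was not tested.

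Some list medians turned sign. Hepatocyte markers in obesity were at 0.0164 with median scaling. Neutrophil markers in lean FXR-K217Q were at 0.19 on probes detected on every array. That filter drops Camp, Ltf, Mpo and Ngp, whose means lay lower in lean FXR-K217Q, so the turn reflects which members were left. Over single arrays left out the neutrophil median was at -0.444 to 0.0742, the latter without lean FXR-K217Q replicate 2. In obese FXR-K217R the interferon response ranged from -0.152 to 0.237 and stellate cell genes from -0.277 to 0.217 over single arrays left out, turning with a call without its replicate 1. With the clock covariate, unfolded protein response genes turned to 0.0458, 0.13 and 0.0201 in lean FXR-K217Q, obese FXR-K217R and obesity, and cell cycle genes to -0.0800 in obese FXR-K217R and -0.17 in obesity. Apart from the members dropped by the filter, the causes were not tested. Of the list medians under alternatives, 2310 kept direction and side of the threshold, 153 lost a call, 78 gained one, 149 moved across 0 with no call and 10 turned with a call before or after. Of named gene values 5522 kept both, 214 lost a call, 44 gained one and 39 moved across 0 with no call.

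With the replicate number as a block, obese FXR-K217R gave 3 genes (Ltf, Ngp and S100a9), obesity 102, and lean FXR-K217Q and the difference 0 each. Arrays of the same number did not pair: their deviations correlated at -0.388 to 0.234 (mean -0.0247, against 0.0133 for other arrays), and 2 of 11 arrays correlated best with their own number. The slide as a block was not run, since the slide is not given in the sources used here.

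Signal over background limits dim genes: 18263 to 19500 probes were detected per array, a gene near background shows less than its true fold, and genes never detected were not tested.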

Other observations

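Both tests in the last paragraph, the comparison of granule genes with other neutrophil genes and the clock index as a covariate, were chosen only after the result was seen.

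All labels give male mice, and the female-biased cytochromes Cyp2b9 and Cyp2b13 differed between arrays of the same group. Cyp2b9 was 9.01 and 10.19 on lean FXR-K217Q replicates 1 and 2 but 6.73 on replicate 3, close to the lean FXR-WT arrays at 7.16 and 5.96. In obese FXR-WT livers Cyp2b9 was 8.12 on replicate 1 against 11.32 and 11.83 on replicates 2 and 3, and in obese FXR-K217R livers it lay between 11.06 and 11.98. Cyp2b13, its paralog, was 5.48, 7.46 and 4.59 in lean FXR-K217Q and 5.10, 8.34 and 9.25 in obese FXR-WT livers. Krt23, a keratin of bile duct cells and stressed hepatocytes, was 9.28, 8.91 and 5.66 in lean FXR-K217Q and 7.63, 9.59 and 9.81 in obese FXR-WT livers. The bile acid enzyme Cyp8b1 was 7.71 on obese FXR-WT replicate 1 against 12.39 and 12.75 on the other two, and Cyp7a1 was 8.88 against 12.16 and 11.81. A1bg, also female-biased, averaged 5.02 ± 0.47 (SD, n = 3) in lean FXR-K217Q against 6.52 ± 0.11 (SD, n = 2) in lean FXR-WT livers (limma adjusted p = 0.166). In obese livers it averaged 5.02 ± 0.26 (SD, n = 3) with FXR-K217R against 5.54 ± 0.37 (SD, n = 3) with FXR-WT (limma adjusted p = 0.993). Its lean and obese FXR-WT means lay further apart than its obese means with FXR-K217R and FXR-WT. A1bg was detected on 1 of 3 lean FXR-K217Q and on 0 of 3 obese FXR-K217R arrays (at least 1.26-fold lower), so these means are near background. It was the 1 list member lower in lean FXR-K217Q adjusted over the list alone. Female-biased genes as a list gave no call in any comparison (7 measured members, camera adjusted p = 1.0 for lean FXR-K217Q, 0.877 for obese FXR-K217R and 0.709 for obesity).

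Kupffer cell markers gave no call either. Their median was 0.04 in lean FXR-K217Q against a mean of -0.19 (camera direction down), -0.24 in obese FXR-K217R and 0.10 in obese FXR-WT livers, with camera adjusted p = 1.0, 0.208 and 0.323. Vsig4, a complement receptor of Kupffer cells, averaged 11.64 ± 0.36 (SD, n = 2) in lean FXR-WT, 10.58 ± 0.38 (SD, n = 3) in lean FXR-K217Q, 11.06 ± 0.71 (SD, n = 3) in obese FXR-WT and 9.93 ± 1.01 (SD, n = 3) in obese FXR-K217R livers. P53 targets had a median of 0.34 in obesity, with Bax at 0.83 and Gdf15 at 0.70 (camera adjusted p = 0.00775, adjusted p = 0.478 with an estimated correlation, call lost without lean FXR-WT replicate 2 at 0.18), and unfolded protein response genes -0.40, with Chac1 at 1.34 and Edem1 at -0.63 (camera adjusted p = 0.0477, adjusted p = 0.812 with an estimated correlation). The unfolded protein call was lost without any 1 of 7 of the 11 arrays, at -0.18 without obese FXR-WT replicate 3 and -0.26 without lean FXR-WT replicate 2. Oxidative phosphorylation and cytosolic ribosomal protein genes stayed near 0 in median, at 0.04 and 0.01 in lean FXR-K217Q, -0.01 and -0.01 in obese FXR-K217R and -0.04 and 0.01 in obesity.

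In lean FXR-K217Q livers 5 granule genes (Mpo, Ela2, now Elane, Ltf, Camp and Ngp) had a mean change of -1.57 (SE 0.13), while S100a8, S100a9 and Retnlg, transcripts of mature neutrophils, had 0.01 (SE 0.36). Both sets were picked from the 11 measured neutrophil markers after their values were seen, so their difference of -1.57 (SE 0.31), against -0.35 (SE 0.28) in obese FXR-K217R livers, restates the split and tests nothing, and a loss of neutrophils of every stage stays open. With the clock index as a covariate a granule gene change of -1.61 (SE 0.14) was left. The slope of that covariate rests mainly on lean FXR-K217Q replicate 3 and obese FXR-WT replicate 1, so it cannot decide on time of collection. Fewer immature neutrophils in lean FXR-K217Q livers may be a candidate explanation, as may fewer neutrophils with S100a8 and S100a9 kept up by monocytes, but no lean gene passed 5% FDR in limma (1113 had an unadjusted p under 0.05) and no count of cells was used here.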
